A study of Homo sapiens with 5 samples.

How the data were processed

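Total RNA of IMR90 fibroblasts expressing RASV12 was depleted of ribosomal RNA and made into libraries with the KAPA RNA HyperPrep kit with RiboErase, per the labels' protocols. Cells were seeded on day 10 after infection, transfected with an antagomir 24 hours later and harvested after a further 24 hours, per the labels. Reads were trimmed with Trimmomatic 0.35, aligned with STAR 2.5.1b to GRCh38 and compared with DESeq2 1.22.2, per the submitters' processing notes. The read counter, its strand setting, the annotation release and the model behind the authors' comparison are not given in the sources used here.

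The deposited table gives, for each gene, a signal per library, which is the read count divided by the library's size factor by the authors, together with the authors' fold change (a linear ratio) and the authors' p-value and adjusted p-value. Every value in each of the 5 deposited columns is a whole multiple of that column's smallest step within 1e-06 (100% of values), so that reads were recovered exactly. The size factors that follow are 1.05 and 1.07 for controls B and C and 1.06, 1.10 and 0.989 for anti-miR-146a A, B and C. The table as used here has 18568 genes, and the authors' adjusted p-values require at least 7535 tested genes where 5593 rows carry one, so it holds part of the genes of the experiment. The read sums given in the report are therefore not full depths. The deposited columns name the antagomir and a letter, and they could be tied to a group but not to a single GEO replicate.

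The tests had been planned on counts. Because the deposited values are normalized, limma was used on log2(value + 1) with its trend option, with the antagomir as the only term, as the plan set for that case. A fold change is therefore on the log2(value + 1) scale, which understates the change of low genes. The plan set no filter for normalized values, so genes with a value of at least 10 in at least 2 libraries were tested, which left 6317, and an adjusted p (Benjamini-Hochberg) under 0.05 was the threshold. Count tests on the recovered reads (edgeR 4.0.16, DESeq2 1.42.0, limma voom) were alternatives. Other versions were limma 3.58.1 and R 4.3.3. Gene classes came from the deposited categories. Positions were checked against GENCODE 29 (GRCh38) and were identical for 17390 of 17390 rows with the same versioned gene ID, and GENCODE 29 gave strands, transcript GC content and length, 3′ UTRs and overlaps.

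Gene lists were fixed before the data were examined. Many fixed members had no row in the table as used here or were too low to test, so list results cover the tested members only. The tested members all have deposited symbols that begin with A to I, so the tested genes are not shown to stand for all genes of the experiment. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over 16 lists. The seed test compared median log2 fold changes of protein-coding genes with and without an 8mer or 7mer match to miR-146a-5p in the longest 3′ UTR, beside 284 control 7mers. The class difference of long non-coding RNAs, which was not planned, was tested over all 10 choices of 2 control libraries. Intervals for that difference come from 2000 resamplings of genes, and genes are not independent replicates. Named genes followed a rule fixed before the data were examined: the 8 highest and 8 lowest genes past the threshold with a mean of at least 20 reads and groups that do not overlap, the 5 highest and 5 lowest long non-coding RNAs by the same rule, up to 4 passing members of each list or else its 2 most abundant, a fixed set of senescence and miR-146a genes, and, where fewer than 4 passed in a direction, the 6 with the smallest unadjusted p. Exceptions are named as such, and a gene that the rule selects is not reported here.

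The alternatives changed the test, scaling, filter (none, or 50 reads in 2 libraries), threshold (0.01 and 0.10), pseudocount (0.1 and 5) and libraries. Added after the data were seen were the class difference, the column letter as a block, the C libraries as a term, both C libraries left out, edgeR with TMM, and a correction of each library for GC content and length (loess, span 0.5). The fits were tested on simulated counts with 200 changed genes. All genes were given the same dispersion (spread beyond counting noise), estimated with the antagomir and the letter as terms. The recovery below may therefore be higher than in the data. Without differences between letters, the test with the antagomir alone, on 6290 genes, recovered 58.8% of genes changed 1.5-fold and 88.3% of those changed 2-fold. With differences between the C libraries and the rest as large as in the data, on 6369 genes, it recovered 0% of both. The model with the C term recovered 54.5% of genes changed 1.5-fold and 88.8% of those changed 2-fold, and the model with the letter as a term 50.5% and 87.8%. The differences were simulated along the split that the C term fits, so this recovery does not test whether that term suits the data.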

Results

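RNA was measured by sequencing in IMR90 cells, a line of normal human lung fibroblasts, that had been infected with a retrovirus carrying RASV12, a constantly active form of the RAS signalling protein that drives fibroblasts into senescence. The cells were then transfected with an antagomir, a modified antisense oligonucleotide that binds and blocks a microRNA. Control libraries received a control antagomir (n = 2, marked B and C in the deposited table) and the others an antagomir against miR-146a (n = 3, marked A, B and C). The comparison asks which transcripts, and long non-coding RNAs above all, depend on miR-146a in RAS-induced senescence. The rows used here held 8556206 and 9283950 reads in the control libraries and 8430859, 8748287 and 8500545 reads in the anti-miR-146a libraries. These sums cover the 18568 gene rows analysed, which are part of each library, so they are not its full depth. Nothing in the labels says that the libraries came from separate cultures, so the p-values below measure only the spread between these libraries, which may be technical.

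The 2 libraries marked C stood apart from the other 3 more than the antagomirs did from each other. The first principal component, with 53.4% of the variance, separated the 2 libraries marked C from the other 3, and the second, with 29.3%, separated the antagomirs. Anti-miR-146a libraries A and B correlated at r = 0.994 across genes, control C and anti-miR-146a C at 0.988, and control B with control C at 0.979. HRAS, the RAS family gene whose reads here would include those of an HRAS transgene, had 3610 and 10250 normalized reads in controls B and C. It had 4265, 4008 and 9631 in anti-miR-146a A, B and C, so it was about 2.54-fold higher in the C libraries and close between antagomirs (log2 fold change −0.15, SE 0.54). No pair of libraries agreed within sampling noise: the smallest chi-square per gene was 4.91, between anti-miR-146a A and B.

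**Figure D1:**
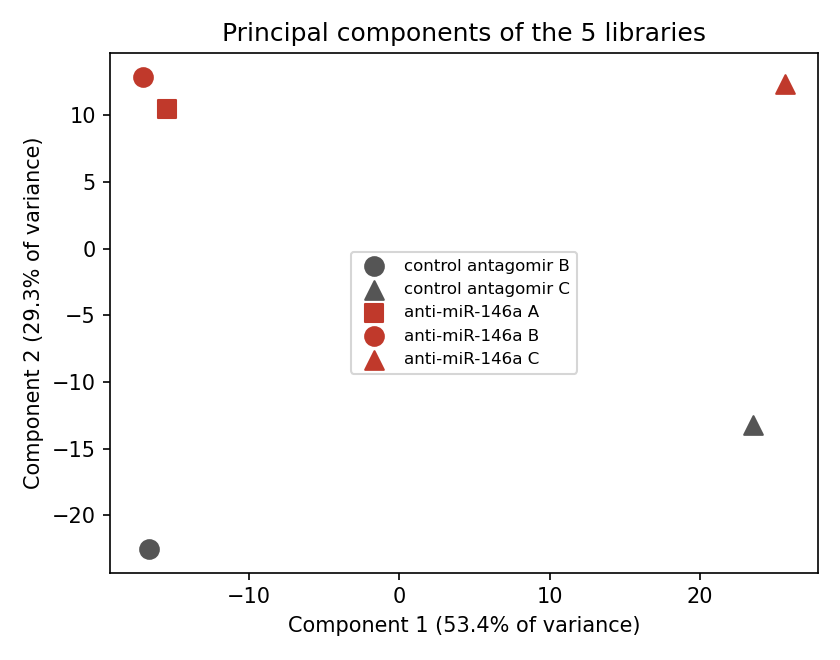
Each point is 1 library, placed by the first 2 principal components of log2(normalized read count + 1) over 6317 genes, with grey for the control antagomir, red for anti-miR-146a and the marker shape for the library's letter. Component 1 (53.4%) parts the C libraries from the rest and component 2 (29.3%) parts the antagomirs.

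Among the 6317 genes tested, the clearest difference in a long non-coding RNA was in AC058791.1, named LINC-PINT in GENCODE 29 (chromosome 7, 130876809 to 130913310, GRCh38), whose bounds on the same strand hold the gene of the microRNA MIR29B1 and part of that of MIR29A. It had 7640 ± 1589 normalized reads (SD, n = 2) with the control antagomir and 17704 ± 315 (SD, n = 3) with anti-miR-146a, 2.34-fold higher (log2 fold change 1.23, SE 0.15). ADAM32, a membrane protein of the disintegrin and metalloprotease family, had 291 ± 34.1 normalized reads (SD, n = 2) in controls and 86.1 ± 8.81 (SD, n = 3) with anti-miR-146a, a log2 fold change of −1.74 (SE 0.17). IL1RN, which encodes the interleukin-1 receptor antagonist, had 123 ± 9.99 (SD, n = 2) against 272 ± 7.84 (SD, n = 3), a 2.21-fold difference. For each of these genes every anti-miR-146a library lay on one side of both controls, but none passed in limma (adjusted p 0.235 for all 3).

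These belong to the 6 genes in each direction with the smallest unadjusted p, none of which passed the adjusted threshold in limma. DESeq2 called 11 of the 12, all but DMBX1, with AC058791.1 at an adjusted p of 1.51e-08, and ADAM32 also passed in limma without anti-miR-146a C (adjusted p 0.0259). The other higher genes were C2orf82 (now SNORC), with 22.9 and 27.1 normalized reads in controls and 79.3, 77.6 and 85.0 with anti-miR-146a, the splicing and RNA decay factor HNRNPD (log2 fold change 0.71, SE 0.10), the antisense gene CTD-3193O13.12 (1.03, SE 0.14) and the homeobox gene DMBX1. DMBX1 had 0 and 1 read in the controls and 24, 15 and 21 reads with anti-miR-146a. The other lower genes were COX19, a factor in the assembly of cytochrome c oxidase (log2 fold change −0.80, SE 0.13), the transcriptional repressor HIC1 (−0.71, SE 0.12), FAM208A (now TASOR), a subunit of the HUSH silencing complex (−0.96, SE 0.18), the antisense gene CTA-29F11.1 (−0.83, SE 0.13) and the histone H3 pseudogene HIST1H3PS1 (−3.46, SE 0.57). Reads of HIST1H3PS1 are uncertain because histone H3 genes are near-identical copies, and those of antisense genes because the strand setting of the counting is not given in the sources used here.

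**Figure D2:**
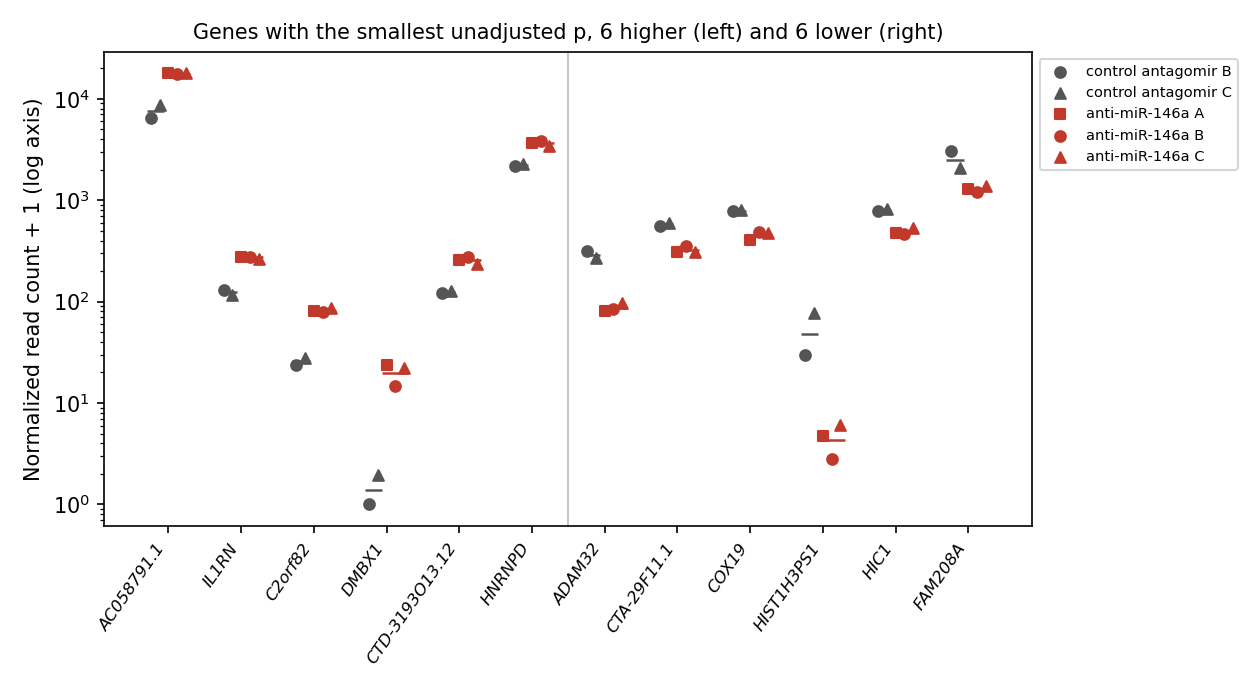
Each point is 1 library's normalized read count plus 1, on a log axis, for the 6 genes higher (left) and the 6 genes lower (right) with anti-miR-146a that had the smallest unadjusted p, and bars give group means of the log values. In all 12 genes the 3 anti-miR-146a libraries lie on one side of both controls, with AC058791.1 at 6516 and 8764 in controls against 17341 to 17894.

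No gene passed the threshold in limma on log2 values: 0 of 6317 had an adjusted p under 0.05, and 715 had an unadjusted p under 0.05. On the reads recovered from the normalized values, edgeR also called 0 genes (710 at an unadjusted p under 0.05), limma voom 0 (705), and DESeq2's Wald test 46 of 15396, of which 31 were higher and 15 lower with anti-miR-146a. In the rows used here, the authors' deposited table gives 144 genes an adjusted p under 0.05, 95 of them higher and 49 lower. These are among the 5593 rows with such a value, which are not all the genes that the authors adjusted over. In the authors' deposited table AC058791.1 has a fold change of 2.32 (adjusted p 4.17e-13), ADAM32 one of 0.296 (adjusted p 2.09e-15) and the Notch ligand DLL4, picked after its value was seen, one of 2.17 (adjusted p 3.97e-06). The treatment of the C libraries moved the count: with them as a term of the model, added after the data were seen, limma called 975 genes (546 higher, 429 lower), and without both C libraries, which leaves 1 control, it called 1555. The split by direction moved too: with that term edgeR gave 454 higher and 502 lower, and limma after GC and length correction 514 and 699. Leaving out anti-miR-146a C alone gave 12 genes, 1 higher and 11 lower, and leaving out any other single library gave 0.

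Long non-coding RNA genes tested here had a higher median fold change than protein-coding genes. This comparison of the classes was chosen after the data were seen. The tested genes come from the part of the experiment's genes used here, so the difference may not extend to other long non-coding RNAs. The median log2 fold change was 0.18 over 782 long non-coding RNA genes and −0.01 over 5171 protein-coding genes, and 66.4% against 48.5% of the genes were higher with anti-miR-146a. The difference of the medians was 0.19, the largest in size among the 10 ways to pick 2 control libraries out of 5, for an exact two-sided permutation p of 0.1, the smallest that this design allows, and against protein-coding genes of matched mean value it was 0.0989. The difference was 0.25 for libraries A and B against control B, as no control is lettered A. Within letters it was 0.27 for library B against control B and 0.10 for library C against control C. No long non-coding RNA gene passed in either direction in limma, 75 were higher and 12 lower at an unadjusted p under 0.05, and none passed when adjusted over the class alone. DESeq2 called 7 as higher and 1 as lower. The rows used here of the authors' deposited table list 13 as higher and 1 as lower at an adjusted p under 0.05. Without control B the difference was 0.08, and without control C it was 0.27.

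**Figure D3:**
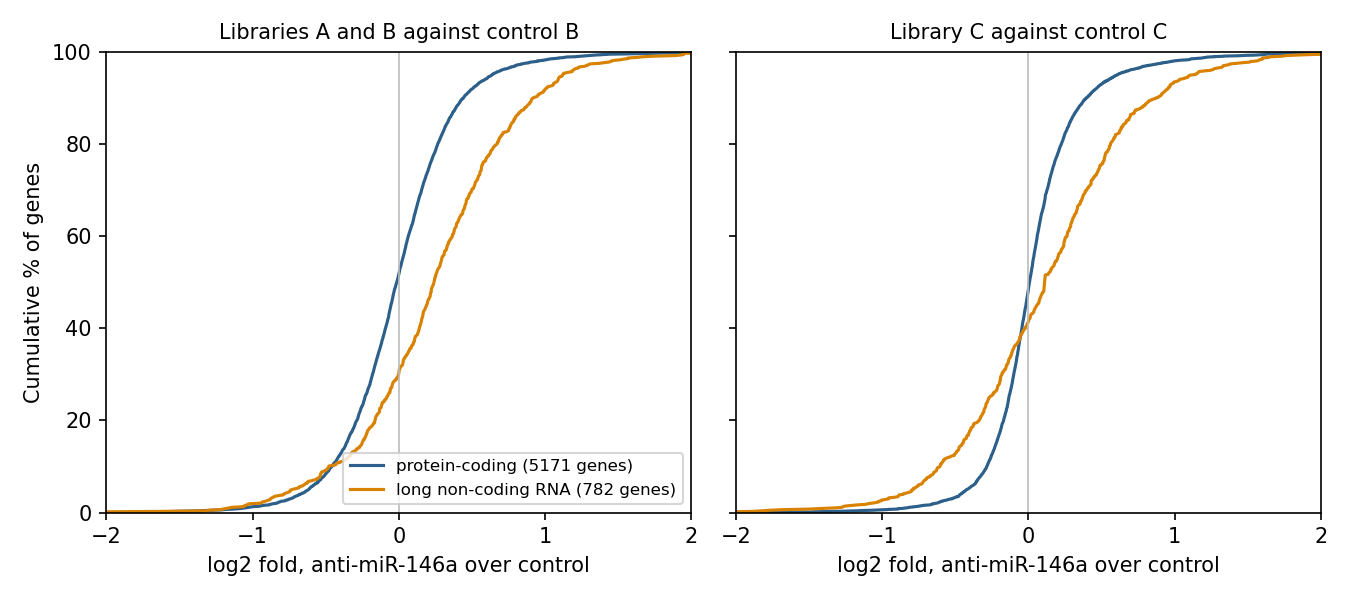
Cumulative share of genes (%) against the log2 fold change of anti-miR-146a over control, for 5171 protein-coding (blue) and 782 long non-coding RNA genes (orange). Libraries A and B are set against control B (left) and library C against control C (right). The orange curve lies to the right of the blue one at its median in both panels, by 0.25 on the left and 0.10 on the right.

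Of the 27 listed miR-146a targets, 10 were tested and 0 passed over all genes in limma. DESeq2 called CXCR4 over all genes (adjusted p 0.038), and in the authors' deposited table it has a fold change of 2.55 (adjusted p 6.79e-04). Adjusted over the list alone in limma, 2 passed: the chemokine receptor CXCR4 was higher and the DNA repair gene BRCA1 lower, and both are named after their values were seen. CXCR4 (chromosome 2, 136114349 to 136118165) had 34.8 ± 10.1 normalized reads in controls (SD, n = 2) and 89.2 ± 16.9 with anti-miR-146a (SD, n = 3), 2.54-fold higher. BRCA1 had 264 ± 33.6 (SD, n = 2) and 172 ± 5.70 (SD, n = 3). The most abundant members were EGFR, at 12178 ± 2559 against 14586 ± 2101, and BCLAF1, at 2883 ± 292 against 2974 ± 320 (SD, n = 2 and n = 3). With camera the list as a whole did not move in one direction against other genes (adjusted p = 0.771), while fry, which asks for changes in either direction within the list alone, gave adjusted p = 0.0116, the lowest of 16 settings that ran up to 0.974. The adaptor and kinase genes IRAK1, TRAF6 and IRAK2, the miR-146a host MIR3142HG, and IL6, NEAT1 and MALAT1 were not analysed here.

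Protein-coding genes with a miR-146a-5p seed match in the 3′ UTR differed little from the rest, with a sign that depended on the comparison. The 1149 genes with an 8mer or 7mer site had a median log2 fold change 0.02 lower than the 3265 genes with none (difference −0.02). With 8mer sites only (266 genes) the difference was −0.03. Within letters this 8mer difference was −0.09 for library B against control B and −0.008 for library C against control C. After correction for GC content and length, added after the data were seen, the difference for 8mer and 7mer sites was 0.0123. A further comparison took the 690 genes with the 7mer that pairs to positions of the seed without the terminal A, or the 8mer. It set them against all 4429 others, which include genes with other seed matches, so it is not like the differences above. The difference was −0.0003, against a median of −0.03 and a 95% range of −0.06 to −0.001 over 284 control 7mers of equal base composition. It lay above that range, with 2.11% of the controls at or above it. With the C libraries as a term it was 0.0001, inside the range of −0.06 to 0.002, with 4.23% of the controls at or above it.

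The secretory and inflammatory lists held no gene that passed, over all genes or adjusted over each list alone. Of 24 senescence-associated secretory factors tested, CXCL8, the chemokine interleukin-8, was the most abundant, at 130361 ± 5906 normalized reads in controls (SD, n = 2) and 116834 ± 14009 with anti-miR-146a (SD, n = 3). IGFBP5 had 69468 ± 16004 and 67191 ± 10456. IL1A, the interleukin-1 alpha gene, had 782 and 2124 in controls B and C and 746, 735 and 2169 in anti-miR-146a A, B and C, so it followed the C libraries and not the antagomir. ICAM1, one of 5 NF-κB response genes tested, did likewise, with 2527 and 5439 against 2351, 2682 and 5191, and IER3 had 31848 ± 185 and 29750 ± 2008. Of 16 type I interferon response genes tested, IFIT3 had 816 ± 287 and 630 ± 70.3, and DTX3L 1012 ± 73.7 and 1114 ± 60.6 (SD, n = 2 and n = 3 throughout). Camera gave these lists adjusted p = 0.677, 0.771 and 0.749.

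Cell cycle and DNA replication genes were lower with anti-miR-146a as a list, the only one of 16 lists tested that passed with camera at a preset correlation (adjusted p = 0.0272), a call lost with an estimated correlation (adjusted p = 0.821). Of its 42 members, 21 were tested, so the result covers only part of the list. Of these 21, 17 were lower and 4 higher, with a median log2 fold change of −0.20. No single member passed in limma over all genes or over the list alone. DESeq2 called CENPF (adjusted p 0.0159) and CENPE (0.0488). CENPF, a kinetochore protein of dividing cells, had 2091 and 1435 normalized reads in controls B and C and 618, 525 and 1053 in anti-miR-146a A, B and C. The mitotic transcription factor FOXM1 instead differed between the C libraries and the rest, with 1091 and 425 in controls and 934, 1010 and 412 with anti-miR-146a. The list also lay lower in the C libraries than in the others (median log2 difference −0.43). The call was also lost after GC and length correction (adjusted p = 0.0753), without control B (0.857), without anti-miR-146a C (0.409), and with fry in one direction (0.865) or either (0.742). It held in 10 of 16 settings, which ran from 6.58e-05 to 0.865.

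The remaining growth and stress lists held no gene that passed in limma, over all genes or adjusted over the list alone, and none was a call with camera on all 5 libraries without a term for the letter. DESeq2 called CHAC1 of the unfolded protein list (adjusted p 0.0443). CDKN1A, the p21 cell cycle inhibitor and a member of both the senescence arrest (13 tested) and p53 target lists (10 tested), had 21370 ± 6760 normalized reads in controls and 27464 ± 3733 with anti-miR-146a. CDKN2A, which encodes p16, had 455 ± 109 and 440 ± 64.4. The chromatin protein gene HMGA1 had 19751 ± 2630 and 19634 ± 2663, and the p53 target AEN 3044 ± 421 and 3184 ± 429. Among 18 RAS-ERK output genes, CCND1 (cyclin D1) had 40562 ± 10442 and 42070 ± 8397, and DUSP6, a phosphatase that dampens ERK, 9177 ± 2042 and 8277 ± 2525 (SD, n = 2 and n = 3 throughout). The RAS-ERK and p53 lists lay higher in the C libraries than in the others (median log2 differences 0.55 and 0.51). Camera gave adjusted p = 0.56, 0.677 and 0.56 for the antagomir comparison in the senescence arrest, p53 and RAS-ERK lists.

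Of 29 replication-dependent histone genes tested, 20 were lower and 9 higher (camera adjusted p = 0.56). With an estimated correlation it was 0.821. At the preset correlation the list passed as lower without control C (0.00357), and its direction turned to higher without control B (0.575) and without anti-miR-146a C (0.652). HIST2H2BE had 3060 ± 213 and 2820 ± 133, and HIST1H1C 2971 ± 1076 and 2548 ± 582 (SD, n = 2 and n = 3). This list was lower in the C libraries by a median log2 difference of −0.60. Matrix genes of fibroblasts differed little: FN1 (fibronectin) had 84802 ± 18341 and 84778 ± 6817, and COL6A3 56371 ± 14262 and 56964 ± 3331, with 11 of 24 tested members lower and 13 higher (adjusted p = 0.677). In the unfolded protein list (13 tested, adjusted p = 0.56), the chaperone HSPA5 was lower in the C libraries, with 50550 and 24938 in controls B and C and 41778, 44893 and 20945 in anti-miR-146a A, B and C, and CANX had 26649 ± 2651 and 26838 ± 817. Of 15 heat shock genes tested, 12 were lower (adjusted p = 0.222, or 0.821 with an estimated correlation, and at the preset one 0.0101 without control C, 0.857 without control B and 0.645 without anti-miR-146a C), with HSP90AA1 at 31680 ± 3207 and 21146 ± 4375 and HSPA8 at 38250 ± 2788 and 34771 ± 1622. In the cholesterol list 8 of 10 tested members were higher (adjusted p = 0.56), and FDFT1 had a log2 fold change of 0.26 (SE 0.18).

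Among proteins of the microRNA pathway (11 tested, adjusted p = 0.791), DDX6 had 9894 ± 443 and 9548 ± 284 and the editing enzyme ADAR 8848 ± 273 and 8182 ± 128 (SD, n = 2 and n = 3). The only microRNA host transcript of its list that was tested, C1orf132 (now MIR29B2CHG), had no adjusted call over all genes and passed adjusted over the list alone, where it stands by itself, with 126 and 139 normalized reads in controls B and C and 231, 277 and 163 in anti-miR-146a A, B and C. In the list of well characterised long non-coding RNAs (13 tested, adjusted p = 0.677), FENDRR had 4634 ± 895 and 5331 ± 1237 and GAS5 2024 ± 225 and 2240 ± 139. LINC-PINT is a fixed member of this list, but AC058791.1, which has that name in GENCODE 29, was not counted in it. Members were matched by deposited or current symbol, and AC058791.1 had no current symbol, so the list results leave it out. GAS5 also belongs to the small nucleolar RNA host genes (5 tested, adjusted p = 0.677), as does C6orf48 (now SNHG32), at 1649 ± 121 and 1468 ± 71.7. Of 12 markers of other cell types in the table, 11 were too low to be tested, and CD68, a macrophage lysosomal protein also found in fibroblasts, had 5.73 and 9.33 in controls and 17.9, 24.6 and 20.2 with anti-miR-146a. CD68 likewise passed only adjusted over the list alone, as its single tested member, and no gene counted in the other 3 lists passed either way. Fry gave the small nucleolar RNA host genes adjusted p = 0.0116 for changes in either direction, the only 1 of 16 settings in which the list passed (0.721 with fry in one direction, 0.821 with camera at an estimated correlation). Mitochondrially encoded genes and ribosomal protein genes were not analysed here.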

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

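The settings with the C libraries as a term or left out, the column letter as a block, edgeR with TMM, GC and length correction and the difference between long non-coding and protein-coding genes were chosen only after results were seen. All 5 counts of genes past the threshold (total, higher, lower, and long non-coding RNA genes higher and lower) were 0 with limma, limma voom, edgeR with any scaling, without a filter, with 50 reads in 2 libraries, at thresholds of 0.01 and 0.10, with pseudocounts of 0.1 and 5, and after GC and length correction alone. DESeq2 gave 46, 31, 15, 7 and 1. Leaving out 1 library gave 0 to 12 genes in total, 0 to 1 higher, 0 to 11 lower, and 0 long non-coding RNAs either way. Where an arm keeps 1 library, it is assumed to vary like the other arm. With the C libraries as a term, limma gave 975, 546, 429, 98 and 12, edgeR 956, 454, 502, 81 and 15, and limma after GC and length correction 1213, 514, 699, 84 and 23. Without both C libraries the counts were 1555, 753, 802, 117 and 16. The planned block by GEO replicate number was not run because the columns carry no such number. With the column letter as a replicate block, they were 636, 357, 279, 80 and 10, and 363, 177, 186, 30 and 7 after GC and length correction. Deviations from the group mean correlated within letters at r = 0.50 for B and 0.66 for C. With 2 controls their deviations are mirror images, so these are not 2 separate agreements. Control B also correlated more with anti-miR-146a A (r = 0.987) than with anti-miR-146a B (0.985). The letters are therefore not shown to pair the libraries, and 597 of the 975 genes called with the C term were also called with the letter block. In the simulation, differences between the C libraries and the rest were enough to end the calls made without a term for them.

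The number of gene lists past the threshold was 1 with camera and with each scaling, and 0 with an estimated correlation, with fry in one direction and after GC and length correction. It was 2 with fry in either direction and with the replicate block, and 3 with the C libraries as a term, with or without GC and length correction. Leaving out 1 library gave 0 to 3. The median difference for seed sites was −0.02, lay between −0.03 and −0.005 when 1 library was left out, and was 0.0123 after GC and length correction. The difference for long non-coding RNAs lay between 0.0839 and 0.268 when 1 library was left out. Beyond what the simulation shows, the cause of these changes was not tested. Of 103 named genes, 20 passed in a planned setting without a term for the letter, and 18 had the other sign in such a setting while not past the threshold. At most 47 of the 103 were put through any planned setting other than DESeq2, so these counts understate the changes over all of them. Genes with about 10 reads, as many long non-coding RNAs here, have counting errors that limit their folds.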

Other observations

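All tests in this part were chosen after the results were seen, including the model used here, limma with the antagomir and the C libraries as terms; the gene lists alone were fixed earlier. It rests on 2 residual degrees of freedom with spread shared across genes, and it compares libraries within the C pair and within the other 3. In it, 975 of 6317 genes passed. The groups did not overlap in 728 of the 975, where chance gives 20% of genes and all tested genes show 30.0%. Calling genes for a difference between these same libraries raises that share, so it is no separate support for the model. Of the 975 genes, 877 were also called by edgeR with the same terms, 800 by limma with the same terms after GC and length correction, and 46 by DESeq2 without the term, which is all of its calls. All 144 genes past the threshold in the rows used here of the authors' deposited table are among the 975. The genes in this and the next paragraph follow the naming rule as applied to this model.

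The chemokine receptor CXCR4, a listed miR-146a target, rose 2.69-fold (limma adjusted p 3.85e-04, higher in 3 of 3 anti-miR-146a libraries), and FADD and EGFR of the same list rose 1.28-fold and 1.25-fold, while BRCA1 was among 2 members that fell (log2 fold change −0.64, SE 0.12); 5 of 10 did not pass. Low-expressed genes were among the largest rises. Examples are HMCN2, from 22.0 and 26.1 normalized reads in controls to 74.6, 79.4 and 217, the B-cell lectin CD22, from 10.5 and 14.9 to 60.4, 44.7 and 82.9, and ACP7 (3.38-fold). CMYA5 (−1.38, SE 0.20) and the kinetochore genes CENPF (−1.26, SE 0.21) and CENPE (−1.17, SE 0.21) fell, CENPF by 1.87 on the log2 scale in libraries A and B against control B, and by 0.45 in the C pair. In the cell cycle list 6 of 21 members fell, CDK1 (−0.69, SE 0.13) and CCNA2 (−0.65, SE 0.12) among them, and none rose (camera adjusted p 7.3e-05, or 0.797 with an estimated correlation). In the histone list 8 of 29 fell, with HIST1H1D at −0.61 (SE 0.11) and HIST1H1B at −0.41 (SE 0.08), and none rose (camera adjusted p 0.0013, or 0.797 with an estimated correlation).

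Secretory genes went both ways: 3 of 24 rose and 3 fell, with CSF3 (0.50, SE 0.09) and HGF (0.29, SE 0.08) up, and CCL20 (−0.76, SE 0.10) and CCL2 (−0.57, SE 0.09) down. In the interferon list IFIT2 (−0.60, SE 0.13) and IFIT3 (−0.41, SE 0.11) fell and CMPK2 (0.54, SE 0.16) rose. The p53 targets DDB2 (1.82-fold) and CDKN1A (1.38-fold) rose, the latter also in the senescence arrest list, where HMGA2 rose and HMGB2 and CDKN2B fell. In the matrix list COL5A1 and ELN rose and CYR61 fell, with 21 of 24 not past the threshold. In the heat shock list HSP90AA1 (−0.57, SE 0.12) and HSPA1A fell (camera adjusted p 0.0262, or 0.797 with an estimated correlation). With the column letter as a block in place of the C term, camera gave the heat shock list 0.127. HBEGF (−0.83, SE 0.08), DUSP5 and FOS of the RAS-ERK list fell and EPHA2 rose. In the unfolded protein list the glutathione-degrading enzyme CHAC1 rose 1.85-fold, and HSP90B1, ATF3 and DNAJC3 were among 4 that fell. AGO1, an Argonaute protein that carries microRNAs, rose 1.35-fold, the only 1 of 11 microRNA pathway genes to pass. Among long non-coding RNAs, 98 rose and 12 fell, and 92 and 11 did when adjusted over the class alone. CTB-25B13.12 (chromosome 19, 1457670 to 1458580) rose 3.75-fold, from 19.1 and 16.8 normalized reads to 60.4, 97.7 and 62.7, AC058791.1 rose 2.40-fold, and DANCR 1.29-fold, while EPB41L4A-AS1 (−0.47, SE 0.11) and BACH1-IT1 (−0.74, SE 0.16) fell. Splits of the libraries that keep 1 control among the C libraries and 1 among the others number 6, and only 1 of them, the real one, gave as many genes: 975 against a highest of 0 in the other 5. With 6 splits a share under 0.05 cannot be reached.

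The excess of long non-coding RNAs among higher genes was weighed against technical explanations. GC content runs with the fold change across genes (Spearman 0.29), from a median log2 fold change of −0.13 in the fifth of genes lowest in GC to 0.09 in the highest, and mostly in pair B (0.404, against 0.0511 in pair C), but correcting each library for GC content and length left the difference at 0.189 (95% interval over genes 0.154 to 0.223). Against protein-coding genes of matched mean value it was 0.0989 (0.0584 to 0.139), so low expression may account for part of it. That interval lies above 0 but resamples genes and not libraries, so it cannot show whether low expression accounts for the whole. Among 237 long non-coding RNA genes that overlap no protein-coding gene the difference was 0.209 (0.161 to 0.296). It was 0.218 among 411 that overlap one on the other strand and 0.00972 among 121 that overlap one on the same strand, so genes without such an overlap show the difference as well. A change in long non-coding RNAs that follows from blocking miR-146a stays open, as does any difference between the cultures, since the exact permutation p cannot go below 0.1.

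The distance of the C libraries from the others also has candidate explanations. Between them, 1089 genes were higher and 777 lower in the C libraries. After GC and length correction 2211 passed in all, against 1866 before, which argues against a trend with GC content as the sole cause. Whether the same genes passed, and what part GC content plays, was not measured. A higher RAS activity in the cells behind the C libraries may be one source: HRAS was 2.54-fold higher there. The RAS-ERK list was also higher with camera (adjusted p 4.51e-04, or 0.301 with an estimated correlation), with 12 of 18 members higher and 2 lower. HRAS is itself among the 12 higher members, so the gene and the list are not separate support. The RAS-ERK list was not alone: p53 targets (9 of 10) and matrix genes (15 of 24) were higher there and histone and cell cycle genes lower (22 of 29 and 11 of 21). No list passed with an estimated correlation (p53 and histones 0.301, matrix and cell cycle 0.661). The labels give all libraries the same times from infection to harvest, but no RAS level per library. A stronger RAS response and a different infection or culture day therefore stay open together.

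A further hypothesis was that transcripts that host microRNAs rise as a class, prompted by AC058791.1, C1orf132 and CTD-3252C9.4, which overlap genes of the miR-29 and miR-23a clusters and all rose. Of 15 long non-coding RNA genes that overlap a microRNA gene on their strand, 4 rose, against 94 of 767 others (odds ratio 2.60, 95% interval 0.59 to 9.0, Fisher's exact test, two-sided p 0.107). The 3 genes that prompted the hypothesis are among these 4, so the count cannot test it, and the median log2 fold change without the C term was 0.11 in the 15 and 0.18 in the others.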
